A study of Mus musculus with 2 samples.

How the data were processed

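The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against H3K4me2, histone H3 dimethylated at lysine 4, a mark found at active and poised promoters and enhancers. Per the labels, the tissue was neural tube of B6NCrl mouse embryos at 13.5 days, pooled from males and females. The 2 samples formed 1 group and were labelled as biological replicates 1 and 2, from separate biosamples. There was no second tissue, age or treatment, so no comparison between conditions was possible. The control libraries named in the labels were not analysed here.

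The authors deposited 4 peak lists on the mm10 assembly (GRCm38). Per the notes deposited beside the lists, each replicate's list was made from that replicate's alignment and its own control. The pooled list was made from both alignments together, and the replicated list was made from the pooled list and both replicate lists. The peak caller, its version, the aligner and the threshold are not given in the sources used here. The lists hold a fold over control per peak, a linear ratio that the authors' caller gave. They also hold the authors' −log10 p and −log10 q per peak and the position of each summit. These are the authors' own values and were used only to describe, rank or filter peaks within 1 list. No read counts were given, so the sequencing depth of each library is unknown and the lists cannot be corrected for it. A deeper library or a stronger enrichment gives more and wider peaks, which limits every comparison of the replicate lists.

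The replicated list was the main list, and both replicate lists gave the spread (mean ± SD, n = 2). Peaks on chromosomes 1 to 19, X and Y were used. Overlaps were computed with a minimum of 1 bp and set beside 100 random placements within chromosomes made with bedtools 2.31.1. Intervals of 95% on shares are exact Clopper-Pearson intervals and cover counting error only, since neighbouring peaks are not independent. Genes were the 21853 protein-coding genes of GENCODE release M21, on the same assembly. A promoter peak was any peak base within 1 kb of a transcription start site (TSS) of a protein-coding transcript. Covered length was the number of bases under peaks within 5 kb either side of the gene's most covered TSS, with a highest possible value of 10001 bp. It can include the peaks of a neighbouring gene. A peak's location was set by its centre, in the order promoter, exon, intron and between genes. Domains were peaks merged across gaps of up to 1 kb.

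The 24 gene lists, 18 consensus sequences, all tests and the alternatives were fixed before the data were examined, except for those named as chosen later. The share of a list with a promoter peak was compared with all other protein-coding genes by Fisher's exact test. The median covered length of a list was compared with 10000 random lists of the same size, which permutes list membership (called a permutation test with random lists). Pairs of lists were compared by a permutation test of the median covered length with 100000 resamples and by Fisher's exact test of promoter peaks, leaving out shared members. Consensus sequences were searched on both strands in windows of 500 bp on the summits of peaks over 10 kb from any TSS. The background was the same number of windows outside peaks on the same chromosome, matched on GC content in steps of 1%. All tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The smallest p the random lists can give is 0.0002 and the smallest the permutations can give is 1e-05. Genes and peaks are not replicates, so these tests describe the 2 samples.

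Differences between the replicate lists are 1 library against 1 library. They are given as percentiles among 10000 lists matched on covered length in 10 bins or, across Hox genes, as correlations, without a p-value. Alternatives were a stricter threshold (authors' −log10 q of at least 5), the pooled list, either replicate list alone, at least 50% of a peak covered, equal numbers of peaks, promoter windows of 2.5 kb, and the annotated 5′ end of each gene as its TSS. Others were windows of 2.5 and 10 kb for covered length, merging gaps of 0 bp and 3 kb, and random lists matched on promoter CpG density in 10 bins. CpG density was taken within 1 kb of the annotated 5′ end of each gene. A gene marked at another TSS was thus matched by a promoter other than the one measured. For the consensus sequences they were windows of 200 bp, windows shifted by 2 to 5 kb and a distance of 2.5 kb. Leaving out occurrences in repeats was added after the data were seen, as were random lists without matching for promoter peaks, other orders of the letters of the CTCF consensus and 3 alternatives for the difference between replicates.

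Named genes followed a rule set in advance. It took the 25 widest domains that hold a protein-coding TSS and are covered in both replicates, the 10 strongest peaks with 1 per domain, and the 5 strongest distal peaks. It also took up to 4 members with the largest covered length in each list, and the members without a promoter peak where there were 5 or fewer, otherwise their number and the first 4 in list order. All 4 Hox clusters with each Hox gene, and Sox2, Olig2, Shh, Isl1, Foxg1 and Myod1, completed it. The most shifted single genes between the replicates were chosen after their values were seen.

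The procedures were tested on simulated data. In 20000 simulated peaks an overlap of 59.65% was recovered exactly. Of simulated lists of 20 genes with raised marking, 90% were called higher in promoter peaks and 95% in covered length, and none of the unchanged lists was called. Lists of 20 genes with lowered marking were called lower in promoter peaks in 85% of cases and in covered length in 0%, so the covered-length test has little power to call a short list lower. For pairs of 20 against 20 genes, 5% were called with no difference and 95% with a wider first list. A planted consensus was called and 0 others were. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9.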

Results

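H3K4me2 was mapped in neural tube from mouse embryos at 13.5 days, an age at which the spinal cord holds dividing progenitors as well as newly formed neurons. The replicate 1 list held 48623 peaks and the replicate 2 list 46018 (mean 47320.5 ± 1842, SD, n = 2). They covered 59.2 and 57.1 Mb of the genome. The authors' pooled list held 50627 peaks over 66.1 Mb. Their replicated list held 38187 peaks over 62.5 Mb, of which 35459 (92.9%) overlapped both replicate lists. Median peak width was 709 bp in replicate 1, 745 bp in replicate 2 and 1107 bp in the replicated list. The authors' median fold over control was 6.01 in replicate 1, 6.93 in replicate 2 and 11.3 in the replicated list. Sequencing depth was not given and is unknown.

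The replicate lists were compared to find which peaks recurred. In replicate 1, 39381 of 48608 peaks on the main chromosomes (81.0%, exact Clopper-Pearson 95% interval 80.7 to 81.4%) overlapped a replicate 2 peak. In replicate 2, 39955 of 46001 peaks (86.9%, 86.5 to 87.2%) overlapped a replicate 1 peak. Placed at random, between 4.28 and 4.83% of replicate 1 peaks and between 4.55 and 5.08% of replicate 2 peaks did so. Together the lists covered 64.3 Mb, of which 52.0 Mb (80.9%) lay under peaks of both.

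Overlap depended on peak strength. Every peak in the 4 strongest deciles of replicate 1 and the 5 strongest deciles of replicate 2 had a partner. In the weakest decile 38.7% (37.3 to 40.1%) of replicate 1 peaks and 54.7% (53.3 to 56.2%) of replicate 2 peaks did. Unshared peaks had a median fold of 2.94 in replicate 1 and 3.10 in replicate 2, against 10.48 and 10.3 for shared peaks. They were also narrow, with median widths of 256 and 250 bp against 973 and 929 bp.

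**Figure D1:**
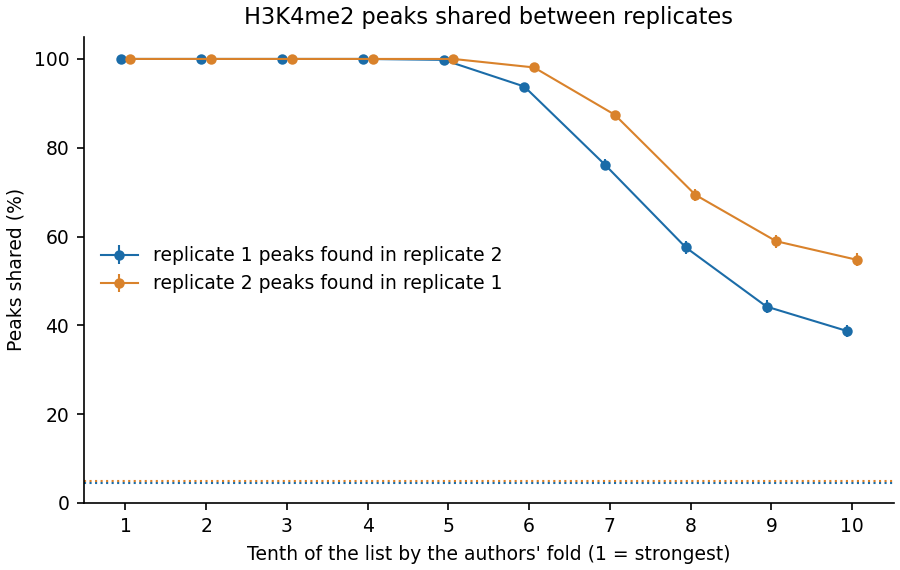
Share of peaks in each replicate list (%) that overlapped a peak of the other, by decile of the authors' fold within the list, strongest first. Points are shares, bars 95% exact intervals and dotted lines the mean of 100 random placements. The share falls from 100% to 38.7% in replicate 1 and to 54.7% in replicate 2.

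The position of peaks relative to genes was compared with random placement. Promoters held 13872 of 38172 peaks (36.3%, 35.9 to 36.8%), against a mean of 2.63% over 100 random placements, a ratio of 13.8. Exons outside promoters held 7.69%, introns 33.2% and the space between genes 22.7% of peaks, against 4.43, 42.0 and 50.9% by random placement. The promoter share was 32.8% ± 1.09 (SD, n = 2) over the replicate lists, and the difference from random placement was far larger than this spread. Promoter peaks had a median fold of 33.9, against 4.70 for intronic and 5.53 for intergenic peaks. In the strongest decile 76.4% of peaks were at promoters, and in the weakest 5.32%. The centres of 9830 peaks (25.8%) lay over 10 kb from any TSS.

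Of the 21853 protein-coding genes, 14670 (67.1%, 66.5 to 67.8%) had a promoter peak. The share over the replicate lists was 67.3% ± 0.21 (SD, n = 2). Both replicates marked 14600 genes, replicate 1 alone 134, replicate 2 alone 69, and neither list 7050. Promoter marking rose with CpG density, from 3.48% of genes in the lowest decile of observed over expected CpG to 99.5% in the highest. The median covered length was 2204 bp over all genes and 2991 bp over genes with a promoter peak.

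Most genes of neural progenitors, which divide along the central canal, were marked. All 16 pan-neural progenitor genes had a promoter peak, with a median covered length of 6693.5 bp (replicate lists 6588.5 ± 205, SD, n = 2). Pax6, a regulator of progenitor patterning, was covered over the full 10001 bp, the RNA-binding protein gene Msi1 over 9513 bp, and the Notch ligand and effector genes Dll1 and Hes5 over 9382 and 8442 bp. Sox2, which maintains the progenitor state (chromosome 3, 34650405 to 34652461, mm10), had 7700 bp covered (7383.5 ± 299, SD, n = 2) within a domain of 18490 bp. All 19 genes of the dorsal progenitor list, which are transcription factor genes apart from the ligand gene Gdf7, were marked, with a median of 6595 bp (6334 ± 93.3), led by Zic1 (10001 bp), Zic4 (9829 bp), Pax3 (9736 bp) and Irx5 (9703 bp). In the ventral progenitor list, which includes components and targets of Sonic hedgehog signalling, 19 of 20 genes were marked and the median was 4479 bp (4020 ± 554). Prdm12 and the hedgehog receptor gene Ptch1 had the full 10001 bp, Nkx6-1 had 8667 bp and Nkx2-2 had 8125 bp. Dbx1 had no promoter peak, with 2070 bp covered nearby. Shh, the ligand secreted by the floor plate (chromosome 5, 28456815 to 28467256), had 4913 bp (4823 ± 116), and Olig2, a factor of motor neuron progenitors (chromosome 16, 91225457 to 91228677), had 3677 bp (2473.5 ± 441).

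Each of these 3 lists was higher than the other genes in promoter peaks by Fisher's exact test (adjusted p = 0.00381 for pan-neural, 0.00154 for dorsal and 0.0098 for ventral genes, 24 lists). Their median covered lengths lay above those of all or nearly all random lists of the same size, whose median was about 2200 bp (permutation test with random lists, adjusted p = 0.000436 each). Against random lists matched on promoter CpG density the covered lengths still passed (the same permutation test, highest adjusted p = 0.00701), but the shares with a promoter peak, which were 87.5, 94.7 and 95% in the matched lists, did not (adjusted p = 0.185, 0.111 and 1).

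Genes of differentiating neurons also carried wide marks. Of 38 transcription factor genes that define spinal neuron subtypes, 37 had a promoter peak and the median covered length was 6545 bp (replicate lists 5873.3 ± 170, SD, n = 2). Lhx1, Tlx3, Lmx1b and Pax2 were covered over 10001 bp. Isl1, a motor and sensory neuron factor (chromosome 13, 116298281 to 116309689), had 6318 bp (5868 ± 25.5). Evx2 lacked a promoter peak in the replicated list but had 1653 bp covered within 5 kb. All 30 pan-neuronal genes were marked, with a median of 6585.5 bp (6287 ± 120). Among them the RNA-binding protein gene Elavl4 and the inhibitory transmitter genes Gad1, Slc32a1 and Slc6a5 reached 10001 bp. Both lists were higher in promoter peaks (Fisher's exact test, adjusted p = 4.05e-05 and 5.21e-05) and in covered length (adjusted p = 0.000436 each). With CpG-matched lists, in which 92.1% of genes were marked, the promoter share of the spinal list no longer passed (permutation test, adjusted p = 0.121).

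Of 20 glial lineage genes, 16 had a promoter peak, a share that did not pass the test (Fisher's exact test, adjusted p = 0.355). Over the pooled list the share was 90% and passed (Fisher's exact test, adjusted p = 0.0351). The median covered length of 4679 bp (replicate lists 4340.5 ± 74.95, SD, n = 2) was higher than in random lists (permutation test, adjusted p = 0.000436). Nfib (10001 bp), Sox10 (9360 bp), Nfia (8930 bp) and Pdgfra (8336 bp) had the longest coverage. Promoter peaks were missing at Gfap, Plp1, Mog and Hepacam.

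Transcription factors of the forebrain and midbrain served as a test of regional identity. Of 28 genes, 27 had a promoter peak, but the median covered length was 2149.5 bp (replicate lists 1826.5 ± 48.1, SD, n = 2). Lhx2 (7012 bp), Neurod6 (6219 bp) and Satb2 (5470 bp) had the longest coverage, followed by Barhl1 (3898 bp), which is also on the spinal list. Otx2, a forebrain and midbrain determinant, had 0 bp in the replicated list and in replicate 1, but a promoter peak and 200 bp in replicate 2, where all 28 genes were marked. Foxg1, a telencephalic factor (chromosome 12, 49382660 to 49386861), had 1496 bp (1381 ± 112). The promoter share was higher than in other genes (Fisher's exact test, adjusted p = 0.0008), though not with the gene 5′ end as the TSS (adjusted p = 0.0629) or with CpG-matched lists (adjusted p = 0.79). The covered length did not differ detectably from random lists (permutation test, adjusted p = 0.909) and was lower than in CpG-matched lists, whose median was 2911 bp (adjusted p = 0.0056).

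The spinal and regional lists were then compared directly. Spinal factors had a median of 6558 bp against 1993 bp for forebrain and midbrain factors, leaving out Barhl1 (permutation test, adjusted p = 1.33e-05, 4 pairs of lists). Promoter peaks did not differ, at 36 of 37 and 26 of 27 genes (Fisher's exact test, adjusted p = 1). Against the master transcription factors of non-neural tissues, the spinal median was 6545 against 1781.5 bp (permutation test, adjusted p = 1.33e-05), and 37 of 38 against 27 of 40 genes had a promoter peak (Fisher's exact test, adjusted p = 0.00138). Pan-neuronal and liver genes had medians of 6585.5 and 0 bp (permutation test, adjusted p = 1.33e-05), with 30 of 30 and 3 of 22 genes marked (Fisher's exact test, adjusted p = 8.07e-11). The raw p of 1e-05 behind each of the 3 covered-length comparisons is the smallest the permutations can give. The same 3 differences passed in each replicate list. The pairs were not matched on promoter CpG density, whose median observed over expected was 0.526 for pan-neuronal and 0.222 for liver genes. Random lists matched on CpG density had a median of 2676 bp for pan-neuronal genes and of 0 bp for liver genes. The liver median of 0 bp is thus no lower than CpG density alone gives.

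**Figure D2:**
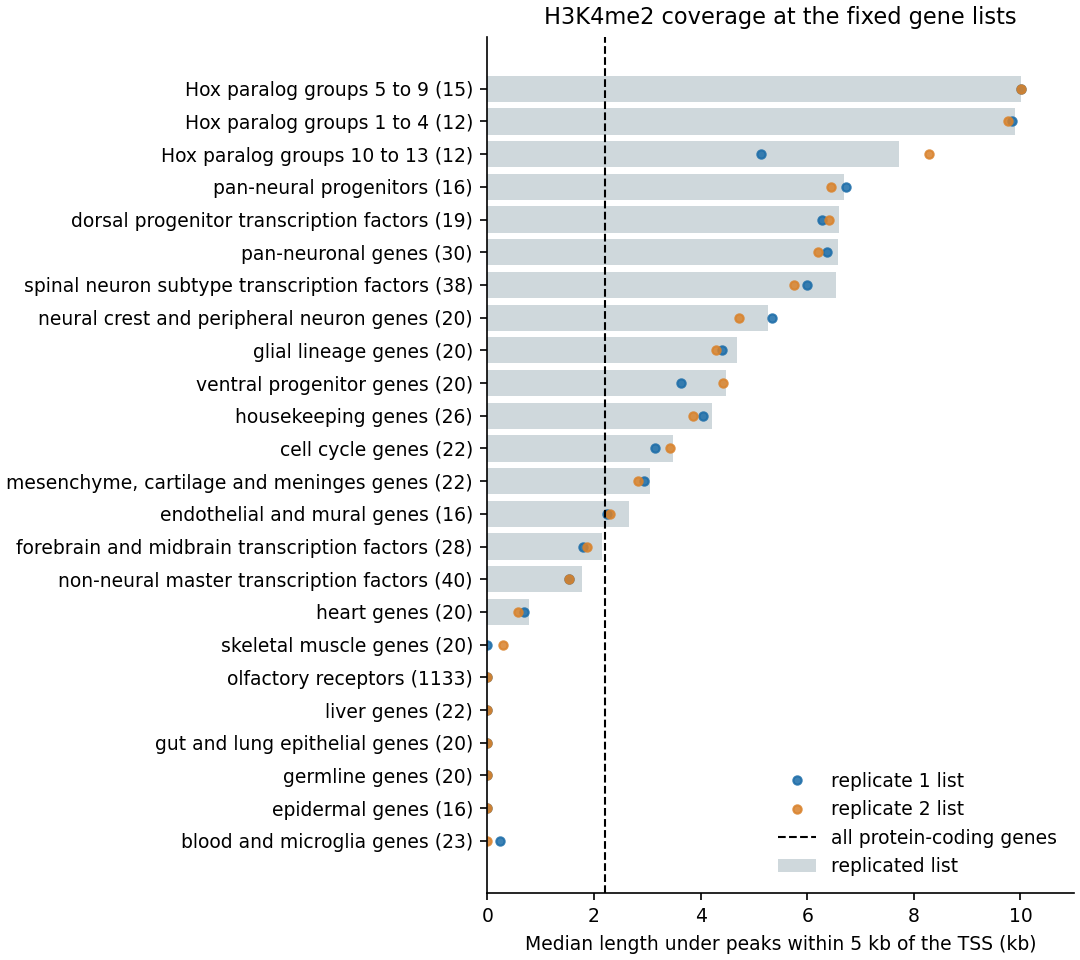
Median length under peaks within 5 kb of the TSS (kb) for each gene list, with the number of genes in parentheses. Bars show the replicated list, points the replicate lists, and the dashed line the median of all protein-coding genes, 2204 bp. The Hox, progenitor and neuronal lists lie to the right of the line, and 7 lists of other tissues have a median of 0 bp.

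Among other cell types that the dissected tissue could hold, neural crest and peripheral neuron genes had wide marks. Promoter peaks were present at 18 of 20 genes and the median covered length was 5255 bp (replicate lists 5029.5 ± 426, SD, n = 2). Tfap2a (9870 bp), Foxd3 (9646 bp), Sox10 (9360 bp) and Tfap2b (9238 bp) led, and Phox2b and Dbh, genes of autonomic neurons, lacked a promoter peak. The list was higher in promoter peaks (Fisher's exact test, adjusted p = 0.0353) and covered length (adjusted p = 0.000436), the former not with CpG-matched lists (adjusted p = 0.616) or with the gene 5′ end as the TSS (80%, Fisher's exact test, adjusted p = 0.19). Of its genes, 3 are on other lists as well, Foxd3 on the spinal, Sox10 on the glial and Hand2 on the non-neural list. The wide marks at Foxd3 and Sox10 thus do not single out neural crest.

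Mesenchyme, cartilage and meninges genes had promoter peaks at 20 of 22 genes (Fisher's exact test, adjusted p = 0.0247), without Col3a1 and Matn1. Their median of 3050.5 bp (2879.3 ± 83.1, SD, n = 2) did not pass (permutation test, adjusted p = 0.0948), except with the pooled list (3504.5 bp, adjusted p = 0.0247) or a 10 kb window (3887 bp, adjusted p = 0.0269), although Foxc1 (6725 bp), Prrx1 (6670 bp), Foxc2 (6537 bp) and Col2a1 (6079 bp) were broadly covered. All 16 endothelial and mural genes had a promoter peak (Fisher's exact test, adjusted p = 0.00381), with a median of 2664.5 bp that did not pass against random lists (permutation test, adjusted p = 0.42). Esam (4930 bp), Pdgfrb (4590 bp), Cspg4 (4247 bp) and Egfl7 (4015 bp) had the longest coverage. CpG-matched lists, which match at the gene 5′ end, had a median of 62.5% marked genes (permutation test, adjusted p = 0.0024). With the gene 5′ end as the TSS 87.5% of the endothelial list was marked, and the difference did not pass (Fisher's exact test, adjusted p = 0.0795). The mesenchyme promoter share likewise did not pass with the gene 5′ end (77.3%, Fisher's exact test, adjusted p = 0.291).

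Genes of muscle, blood, internal organs, epidermis and germline were sparsely marked. Of 20 skeletal muscle genes 5 had a promoter peak (adjusted p = 0.000371), of 23 blood and microglia genes 5 (adjusted p = 4.99e-05), of 22 liver genes 3 (adjusted p = 2.61e-06), of 20 gut and lung epithelial genes 4 (adjusted p = 6.99e-05), of 16 epidermal genes 4 (adjusted p = 0.00137) and of 20 germline genes 2 (adjusted p = 2.14e-06), all lower than other genes by Fisher's exact test. Olfactory receptor genes had a promoter peak in 3 of 1133 cases. Of 20 heart genes 9 were marked, which did not pass (Fisher's exact test, adjusted p = 0.0582) except with the gene 5′ end as the TSS, where the share was 30% (adjusted p = 0.00351). With CpG-matched lists the blood and epidermal differences did not pass (permutation test, adjusted p = 0.249 and 0.185).

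Single members of these lists departed from their group. In the muscle list Mylpf had 4998 bp, Actn3 2148 bp and Myod1, the myogenic master regulator (chromosome 7, 46376474 to 46379099), 2011 bp (1533.5 ± 10.6, SD, n = 2). Acta1 had 2193 bp within 5 kb but no promoter peak, as did 14 more genes of that list, including Myf5, Myog and Mymk. Runx1, a regulator of blood formation that sensory neurons also use, had 7572 bp, ahead of Epor (2713 bp), Ikzf1 (2312 bp) and Klf1 (1856 bp). Promoter peaks were missing at 18 blood genes, among them Gata1, Hbb-bt, Hbb-bs and Hba-a1. In the liver list Apoa2 had 2356 bp without a promoter peak, Foxa3 2310 bp, Trf 1624 bp and Apoa1 1575 bp, and the 19 without a promoter peak included Alb, Afp and Apob. Ryr2 (4019 bp), Gata6 (3983 bp), Myl3 (3720 bp) and Tnni3 (3296 bp) led the heart list, with Nkx2-5, Myh6, Myh7 and Myl7 among 11 without a promoter peak.

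Sox17 (3894 bp), shared with the endothelial list, led the gut and lung genes before Sftpc (2339 bp, no promoter peak), Epcam (1692 bp) and Cdx1 (836 bp). The 16 without a promoter peak began with Vil1, Fabp1, Fabp2 and Cdh17. Epidermal coverage was longest at Grhl3 (2728 bp), Krt10 (2482 bp), Sfn (1752 bp) and Ovol1 (1707 bp), and Krt1, Krt5, Krt14 and Krt15 were among 12 genes without a promoter peak. Germline genes with the longest coverage were Tnp2 (3167 bp) and Gdf9 (2609 bp), neither with a promoter peak, then Tex14 (2200 bp) and Dazl (1081 bp). The other 16 genes without a promoter peak included Ddx4, Tnp1 and Prm1. The liver, gut and lung, and olfactory lists were lower in covered length (permutation test, adjusted p = 0.0429, 0.0496 and 0.000436), and none of these 3 passed against CpG-matched lists (adjusted p = 1, 0.613 and 1). With a 2.5 kb window liver and gut and lung genes did not pass (permutation test, adjusted p = 0.071 and 0.0758), and at the stricter threshold gut and lung genes did not (adjusted p = 0.0531). Muscle, blood, epidermal and germline medians of 0 bp did not pass (permutation test, adjusted p = 0.0501, 0.0587, 0.0594 and 0.0534), in a test with little power to call short lists lower. Germline genes were lower against CpG-matched lists (permutation test, adjusted p = 0.0398), with the pooled list (adjusted p = 0.0443), in the replicate 1 list alone (adjusted p = 0.0486) and with a 10 kb window (adjusted p = 0.0276). Blood genes were lower with the pooled list (permutation test, adjusted p = 0.0483) and a 10 kb window (adjusted p = 0.0341), epidermal genes with that window (adjusted p = 0.0341) and muscle genes in the replicate 1 list alone (adjusted p = 0.045).

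All 26 housekeeping genes had a promoter peak (Fisher's exact test, adjusted p = 0.000189) and a median of 4204.5 bp (replicate lists 3944.5 ± 130, SD, n = 2), higher than random lists (adjusted p = 0.0008). Rpl13a (7375 bp), Polr2a (6553 bp), Ywhaz (6261 bp) and Actb (5718 bp) had the longest coverage. All 22 cell cycle genes were marked (Fisher's exact test, adjusted p = 0.000734), with 3472.5 bp (3286.3 ± 190; adjusted p = 0.0236), led by Ccnd2 (8081 bp), Ccnd1 (6933 bp), Mcm2 (5511 bp) and Mcm7 (4574 bp). CpG-matched lists had 92.3% of genes marked for housekeeping and 100% for cell cycle genes, which left little or no room to call a promoter share higher, and neither passed (permutation test, adjusted p = 0.111 and 1). The cell cycle covered length did not pass against CpG-matched lists (permutation test, adjusted p = 0.365) or with a 10 kb window (adjusted p = 0.0952).

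Non-neural master transcription factor genes, 36 of which are also on other lists, were marked at 27 of 40 genes (Fisher's exact test, adjusted p = 1). Their median of 1781.5 bp (1529 ± 10.6, SD, n = 2) did not pass against random lists (permutation test, adjusted p = 0.355). Against CpG-matched lists both values were lower, with 80% of genes marked (permutation test, adjusted p = 0.0294) and 2546 bp (adjusted p = 0.0048) in the matched lists. Runx1, Foxc1, Prrx1 and Foxc2 had the longest coverage, and Myf5, Myog, Gata1 and Spi1 were the first of 13 without a promoter peak. Across the 24 lists, 14 were higher and 7 lower in promoter peaks, and 12 were higher and 3 lower in covered length. Random lists without matching, a test of promoter peaks chosen after the data were seen, also gave 14 and 7. Random lists with CpG matching gave 4 and 6 for promoter peaks and 11 and 3 for covered length.

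Hox genes, which set position along the body axis and are numbered from head to tail, were examined by cluster and paralog group. Peaks covered 93.0% of HoxA (chromosome 6, 52155590 to 52260880, mm10; replicate lists 90.5% ± 2.73, SD, n = 2) and 89.7% of HoxC (chromosome 15, 102921103 to 103036852; 86.6% ± 8.37). HoxD (chromosome 2, 74668310 to 74765142) was covered over 80.9% (78.4% ± 3.02) and HoxB (chromosome 11, 96194316 to 96368256) over 60.5% (59.6% ± 0.54). All 12 genes of groups 1 to 4, all 15 of groups 5 to 9 and all 12 of groups 10 to 13 had a promoter peak. Median covered lengths were 9903.5 bp (9801.8 ± 62.6), 10001 bp (10001 ± 0) and 7716 bp (6712.5 ± 2230).

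At the head end of the clusters Hoxb1 had 1929 bp, Hoxd1 2882 bp and Hoxa1 8973 bp. The full 10001 bp was covered at Hoxa2, Hoxa3, Hoxb3, Hoxd3, Hoxb4, Hoxa5, Hoxb5, Hoxc5, Hoxa6, Hoxb6, Hoxc6, Hoxa7, Hoxb7, Hoxb8, Hoxc8, Hoxa9, Hoxc9, Hoxa10 and Hoxd10. Hoxb2 (9604 bp), Hoxb9 (9688 bp), Hoxc4 (9849 bp), Hoxa4 (9878 bp), Hoxc10 (9887 bp), Hoxd8 and Hoxd9 (9923 bp each) and Hoxd4 (9929 bp) came close. Group 11 genes Hoxd11, Hoxa11 and Hoxc11 had 9153, 9470 and 9875 bp. At the tail end Hoxc12 had 6279 bp (5125.5 ± 3491), Hoxd12 4269 bp (3721.5 ± 2368), Hoxc13 3802 bp (3016.5 ± 2856), Hoxd13 2071 bp (2070.5 ± 1091), Hoxa13 1586 bp (1311.5 ± 305) and Hoxb13 978 bp (849.5 ± 129).

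The 3 Hox lists were higher than other genes in promoter peaks (Fisher's exact test, adjusted p = 0.0149, 0.00616 and 0.0149) and covered length (adjusted p = 0.000436 each). Groups 1 to 4 and 10 to 13 differed by 2187.5 bp, which did not pass (permutation test, p = 0.125). In the replicate 1 list alone the difference was 4710 bp (permutation test, p = 0.0327) and in the replicate 2 list 1468.5 bp (p = 0.11). In the replicate 1 list 11 of 12 genes of groups 10 to 13 had a promoter peak, which did not pass (Fisher's exact test, adjusted p = 0.13). CpG-matched lists had 93.3 and 100% of genes marked for groups 5 to 9 and 10 to 13, which left little or no room to call these promoter shares higher (permutation test, adjusted p = 1 each). Neighbouring Hox genes share peaks, so they are not independent.

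**Figure D3:**
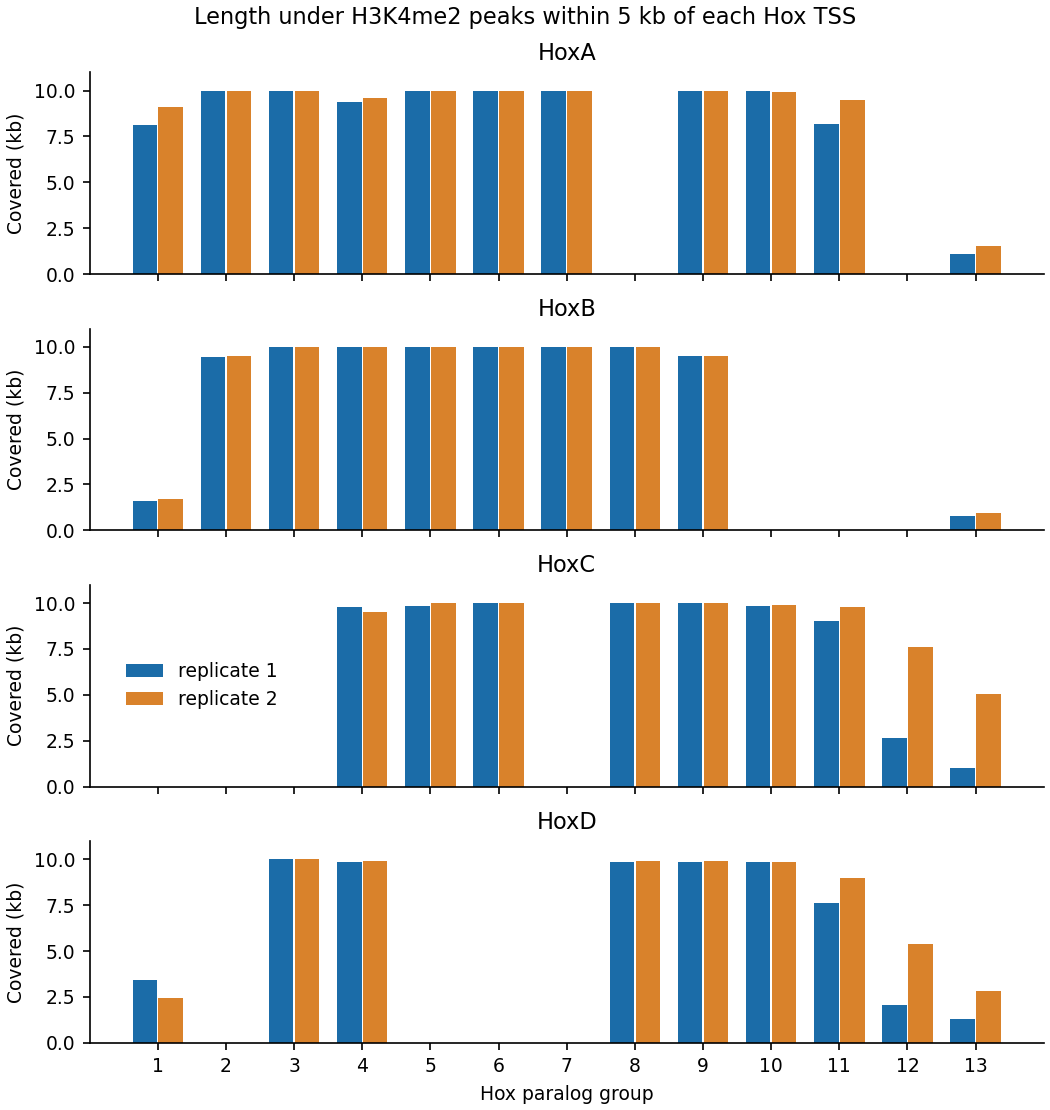
Length under H3K4me2 peaks within 5 kb of each Hox TSS (kb), by paralog group, in replicate 1 and replicate 2. An empty position is a paralog group without a gene in that cluster. The replicate bars differ most at Hoxc12 (2657 and 7594 bp), Hoxc13 (997 and 5036 bp) and Hoxd12 (2047 and 5396 bp).

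Merged across gaps of up to 1 kb, the replicated peaks formed 31835 domains. Of these 2039 were wider than 5 kb, 229 wider than 10 kb and 29 wider than 20 kb. The replicate lists gave 1958 and 1831 domains over 5 kb (1894.5 ± 89.8, SD, n = 2). Domains over 5 kb held 23.4% of all covered bases, and 93.5% of them contained a protein-coding TSS, against 40.04% of narrower domains. The count depended on merging, with 1311 domains at a gap of 0 bp.

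The 4 widest domains lay in the Hox clusters. They spanned 100.6 kb at Hoxc4 to Hoxc11 (chromosome 15, 102941952 to 103042549), 99.3 kb at Hoxa1 to Hoxa11 (chromosome 6, 52154692 to 52253992), 93.4 kb at Hoxb2 to Hoxb9 (chromosome 11, 96263069 to 96356494) and 64.1 kb at Hoxd3 to Hoxd11 (chromosome 2, 74678068 to 74742146). The replicate lists covered 97.4 ± 2.27, 94.7 ± 2.78, 91.9 ± 0.70 and 62.0 ± 1.22 kb of them (SD, n = 2). Next came the shared domain of Zic4 and Zic1 (40.2 kb, chromosome 9, 91348865 to 91389076), Pou3f3 (31.6 kb), Ebf3 (28.9 kb) and Bcl11a with A830031A19Rik (28.0 kb). Nr2f2 (26.5 kb), Ptch1 (26.2 kb), Zfhx3 (25.7 kb), Nr2f1 (25.1 kb), Meis2 (25.003 kb), Pax6 (23.8 kb), Lhx1 with Aatf (23.7 kb) and Nfib (23.2 kb) followed. The rest of the 25 widest were Pou3f2 (22.9 kb), Pax2 (22.2 kb), Lmx1b (21.7 kb), Skor1 (21.6 kb), Tshz1 with Zadh2 (21.4 kb), Tshz3 (20.8 kb), Notch1 (20.3 kb), Setd1b with Rhof (20.2 kb) and Bahcc1 (20.2 kb).

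Among genes with a promoter peak, 15 of 16 pan-neural progenitor genes lay in a domain over 5 kb, against 14.9% of other marked genes (Fisher's exact test, adjusted p = 4.46e-11). The count was 25 of 30 for pan-neuronal genes (adjusted p = 3.35e-15), 23 of 37 for spinal factors (adjusted p = 4.13e-10), 11 of 19 for dorsal genes (adjusted p = 5.8e-05) and 8 of 19 for ventral genes (adjusted p = 0.00872) by Fisher's exact test. Glial genes were in such domains in 10 of 16 cases, neural crest genes in 12 of 18, housekeeping genes in 10 of 26, and Hox genes in 10 of 12, 15 of 15 and 8 of 12 for groups 1 to 4, 5 to 9 and 10 to 13. These 11 lists were higher and 0 were lower by Fisher's exact test. Neighbouring Hox genes share domains, with 10 Hox genes in the widest domain of HoxA, so the Hox counts do not rest on independent genes. Forebrain and midbrain factors lay in a wide domain in 2 of 27 cases (Fisher's exact test, adjusted p = 0.714).

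The strongest peaks were ranked by the authors' fold within the replicated list. Egr1, an immediate early gene, had the highest, 74.5 (chromosome 18, 34858884 to 34863900), with 63.5 and 70.2 at the overlapping peaks of replicates 1 and 2. The cell cycle regulators E2f8 (71.2, chromosome 7, 48880262 to 48882842) and E2f2 (70.5, chromosome 4, 136171395 to 136174636) were next, then Ldb1, a cofactor of LIM homeodomain factors (69.9, chromosome 19, 46035855 to 46046988). The summit at Kmt2d, which encodes an H3K4 methyltransferase, was intronic (69.4, chromosome 15, 98867111 to 98873329). Tysnd1 (68.9), Usp43 (68.7), Ccdc86 (67.7), Col27a1 (67.6) and Tbc1d1 (67.3) completed the 10, all with promoter summits.

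The 5 strongest distal peaks had folds between 56.0 and 58.4. The first (chromosome 3, 96499012 to 96503831) lay 22.3 kb from the TSS of Hfe2, with BC107364 on the other side. The second (chromosome 10, 120551459 to 120553576) lay between Hmga2, 76.1 kb away, and Msrb3, and the third (chromosome 9, 77654742 to 77656268) in an exon 19.04 kb from Klhl31, with Gclc on the other side. The last were between genes 108 kb from Shq1 with Rybp on the other side (chromosome 6, 100562453 to 100564483) and in an intron 50.3 kb from Phactr1, with Tbc1d7 on the other side (chromosome 13, 42915682 to 42917976). Nearness does not show which gene a distal peak acts on.

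Consensus sequences were counted in 9784 distal peak windows and as many background windows, both with a mean GC content of 49.8%. The homeodomain site TAATTA was in 16.3% of peak and 7.12% of background windows (ratio 2.28, Fisher's exact test, adjusted p = 8.58e-89), and its LHX form TAATTAR in 13.6 and 6.01% (2.26, adjusted p = 3.29e-71). The POU octamer ATGCAAAT was in 5.11 and 2.26% (ratio 2.26, Fisher's exact test, adjusted p = 3.2e-26), and the bHLH factor E-box CAGCTG in 35.0 and 26.3% (1.33, adjusted p = 2.13e-39). The SOX site WWCAAWG was in 48.8 and 40.3% (ratio 1.21, Fisher's exact test, adjusted p = 5.86e-32), but against shifted windows it was lower (0.946, adjusted p = 0.000266). The shifted windows were not matched on GC content, with a mean of 44.4% against 49.96% in the peak windows. Against them the ratios of TAATTA, TAATTAR and ATGCAAAT also fell, to 1.12, 1.16 and 1.48, and still passed (Fisher's exact test, adjusted p = 0.00087, 0.000266 and 4.3e-08). The RFX site GTTGCCATGG, of factors that act in ciliated cells, was in 1.05 and 0.296% (ratio 3.55, Fisher's exact test, adjusted p = 1.26e-10). With repeats left out, a test chosen after the data were seen, these 6 were higher too, with ratios from 1.51 for SOX to 5.11 for RFX and of 3.903 for POU. Here and below, that setting was not corrected for the amount of sequence left outside repeats. It raised the ratio of every sequence found in both peak and background windows. It therefore cannot tell a higher frequency from more sequence left to search. The p-values were adjusted over 18 sequences.

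The insulator protein CTCF's site CCASYAGRKGGC had the highest ratio of those called, 10.1, at 3.60 and 0.358% (Fisher's exact test, adjusted p = 2.28e-67). It fell to 0.867 in windows of 200 bp, since the sites lay mostly over 100 bp from the summits. The sites chosen for factors of other tissues gave mixed results and are no strict control. Gata2 and Gata3 are on the spinal list, and sensory neurons also use Runx1. MEF2 (1.18 and 0.399%, ratio 2.95, adjusted p = 1.17e-09) and ETS-RUNX (9.90 and 8.02%, ratio 1.23, adjusted p = 8.24e-06) were higher by Fisher's exact test, MEF2 not against shifted windows (1.32, adjusted p = 0.0735). GATA, HNF4, HNF1 and p53 did not pass (Fisher's exact test, adjusted p = 0.92, 0.404, 1 and 1), but the calls for GATA and HNF4 depended on the setting. GATA was lower with the pooled list (0.87, Fisher's exact test, adjusted p = 0.00935), against shifted windows (0.75, adjusted p = 2.94e-06) and in the replicate 2 list alone (0.875, adjusted p = 0.0285), and higher with repeats left out (1.19, adjusted p = 0.0192). HNF4 was lower with the pooled list (0.634, Fisher's exact test, adjusted p = 0.0106) and against shifted windows (0.506, adjusted p = 0.00087). The TEAD site passed narrowly (ratio 1.05, Fisher's exact test, adjusted p = 0.0446), and its call depended on the setting. It did not pass in either replicate list alone, with the pooled list, in windows of 200 bp, against shifted windows or at a distance of 2.5 kb (Fisher's exact test, lowest adjusted p = 0.058), but was higher with repeats left out (1.38, adjusted p = 6.29e-31). The nuclear receptor site TGACCT was lower, at 21.8 and 28.5% (ratio 0.766, Fisher's exact test, adjusted p = 2.37e-26), and less so with repeats left out (0.935, adjusted p = 0.0208). The other bHLH factor E-box, CAGATG, and the NFI and AP-1 sites did not pass (Fisher's exact test, adjusted p = 0.344, 0.0734 and 0.13), but each passed under some settings. CAGATG was higher with the pooled list (1.04, Fisher's exact test, adjusted p = 0.0149), against shifted windows (1.06, adjusted p = 0.00239) and with repeats left out (1.35, adjusted p = 1.47e-42), and AP-1 was lower with the pooled list (0.905, adjusted p = 0.0155). NFI passed under 6 of its alternatives, with ratios between 2.86 and 11 (Fisher's exact test, adjusted p between 0.00149 and 0.0434), among them both replicate lists alone. In total 10 sequences were higher and 1 lower. Each TAATTAR match contains TAATTA, so these are not independent, and peak windows held 12.6 CG pairs against 6.79 in the background despite the matched GC content.

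**Figure D4:**
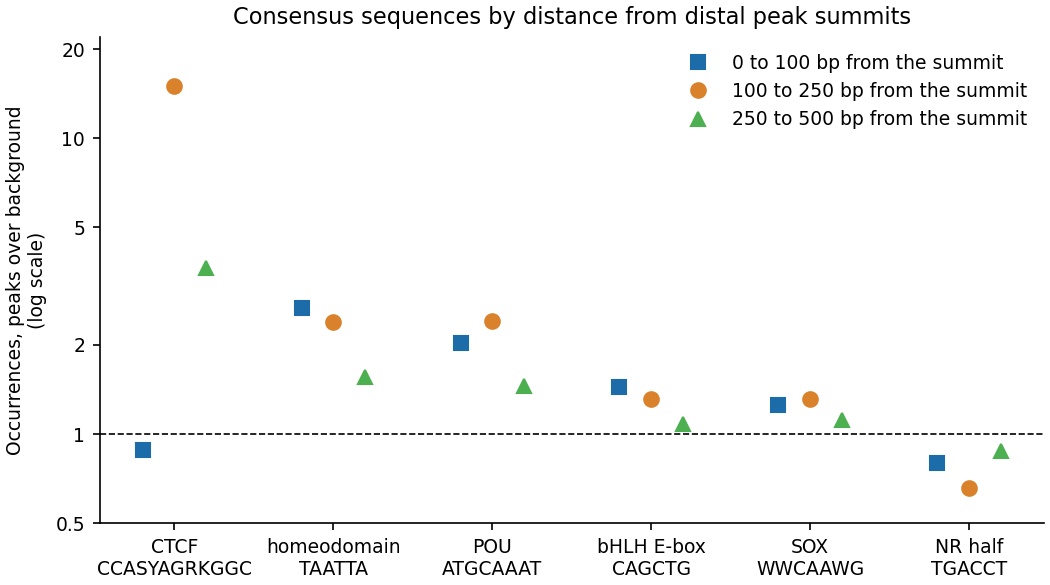
Occurrences of 6 consensus sequences at 3 distances from the summits of distal peaks, as the ratio of peaks to background windows (log scale). The dashed line is a ratio of 1. CTCF has a ratio of 0.882 within 100 bp of the summit, 15 at 100 to 250 bp and 3.63 at 250 to 500 bp, while the homeodomain site is highest within 100 bp (2.68).

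Peaks per Mb were compared between chromosomes, since the tissue was pooled from both sexes. Autosomes carried 15.5 peaks per Mb of the replicated list, between 11.5 and 23.8 on single autosomes. The X chromosome carried 6.17 and the Y chromosome 0.125. The replicate lists gave 19.8 and 18.7 on autosomes and 7.46 and 7.17 on X for replicates 1 and 2. No test was made, and the rates were not corrected for gene density or for how uniquely reads map. These rates therefore do not show an effect of sex.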

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

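Both results here are counts of peaks outside the main measurement and no test was chosen after they were seen. Of the 50627 peaks in the pooled list, 12440 (24.6%) are missing from the replicated list. They have a median fold of 2.52 and a median width of 261 bp, against a fold of 11.3 for those kept. Of them 4580 overlap neither replicate list, 4631 replicate 1 only, 3126 replicate 2 only and 103 both. The results on genes, domains and sequences leave them out, except under the pooled-list alternative.

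The replicated list also holds 15 peaks on unplaced or unlocalised scaffolds, which carry no gene result here. The scaffold GL456233 of the X chromosome holds 7 of them, with a highest fold of 17.8, and replicates 1 and 2 hold 7 and 9 peaks there. No explanation was tested for either result.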

How the results depend on the processing

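The alternatives were set before the data were examined, except for the tests that leave out repeats or genes without coverage, that use random lists without matching for promoter peaks or reorder the CTCF consensus, and those with a 10 kb window or stricter threshold on the difference between replicates, which were chosen after the results were seen. Of 125 alternative values of the main results, 89 stayed the same, 35 moved and 1 gained significance. Staying the same meant within the replicate spread or interval for a share, within a factor of 1.5 for a count, and on its side of the threshold for a test. With no depth in the files, effects of sequencing depth could not be tested. No paired analysis was possible because there is 1 group. Ratios could not be given where the background count was 0, which was so for HNF1 except at a distance of 2.5 kb and, in windows of 200 bp, for NFI and p53. Except where stated, the cause was not tested.

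With 50% of a peak required, 75.6% of replicate 1 and 82.5% of replicate 2 peaks were shared. With −log10 q of at least 5 the shares were 90.1 and 92.3%, the weakest replicate 1 decile was shared at 50.2%, promoters held 38.3% of peaks, genes outside promoters 39.3%, and autosomes 14.6 peaks per Mb. The pooled list gave 28.9% at promoters, 47.1% in genes outside them, 24.0% between genes and 67.9% of genes with a promoter peak. Promoter windows of 2.5 kb gave 46.6, 31.4, 21.9 and 68.3%, and the gene 5′ end gave 28.8 and 48.5% at and outside promoters and 64.3% of genes marked, which follows from how the windows are drawn. Leaving out each replicate gave 32.1 to 33.6% at promoters, 44.5 to 45.6% in genes, 21.9 to 22.4% between genes and 67.1 to 67.4% of genes marked.

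Lists higher in promoter peaks numbered 14 by Fisher's exact test, 14 with random lists without matching and 4 with CpG-matched random lists. Lists lower in covered length numbered 3, against 5 with the pooled list, 1 with a 2.5 kb window, 6 with 10 kb, and 3 to 5 without each replicate. The Hox difference ranged from 1468.5 to 4710 bp without each replicate and passed only without replicate 2. A merging gap of 0 bp left 1311 wide domains. Sequences lower in distal peaks numbered 1, against 4 with the pooled list, 4 with shifted windows, and 1 to 2 without each replicate.

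Directions turned as follows. Non-neural factors were below the other genes in promoter peaks at the stricter threshold (65%) and with the gene 5′ end (57.5%). With CpG matching their share of 67.5% was below the 80% of the matched lists. Forebrain and midbrain covered length was above random lists with the pooled list (2291 bp) and a 10 kb window (2456.5 bp), without passing. Ratios turned for SOX with shifted windows (0.946), CTCF at 200 bp (0.867) and TEAD without replicate 1 (0.998 to 1.03 without each replicate). They also turned for AP-1 (1.06), GATA (1.19) and HNF4 (1.05) with repeats left out, of which GATA passed as higher. The setting without repeats was not corrected for the sequence left to search. Of the alternatives for the covered length of 119 named genes, 377 stayed within the replicate spread and 337 moved.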

Other observations

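The comparison of replicates was made after the lists were seen, and of the tests here those of overall sensitivity, of other transcription factors, of base composition and of sensory ganglion genes with coverage were chosen after the result was seen. The tests on all sensory ganglion genes listed, paralog groups 1 to 9, repeats and distance were set before their own results were seen, although the correlation over all 39 Hox genes was known when groups 1 to 9 were chosen. Differences between replicates compare 1 library with 1 library. The design has 1 group, so no biological explanation from the design was tested.

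The replicates differed in covered length at single gene groups. Over 15485 genes the median difference, replicate 2 minus replicate 1, was -48 bp, with 5th and 95th percentiles of -553 and 391.8 bp. Ventral progenitor genes were wider in replicate 2 in 13 of 20 cases (median 149 bp, percentile 99.9 among matched lists), dorsal genes in 14 of 19 (132 bp, 99.4), forebrain and midbrain factors in 19 of 28 (101.5 bp, 99.9) and cell cycle genes in 14 of 22 (119 bp, 99.6). With a 10 kb window the dorsal value was 17 bp, at percentile 87.55, and at the stricter threshold the ventral value was 70 bp, at 97.6. Endothelial genes were wider in replicate 1 in 11 of 16 (-252.5 bp, percentile 0.31), but at the stricter threshold their percentile was 15.4. Glial genes (-187 bp, 2.12) and heart genes (-41 bp, 2.06) were also wider in replicate 1, but with a 10 kb window their percentiles were 5.68 and 7.56, and at the stricter threshold that of glial genes was 19.6. Foxj1, a gene of ciliated and floor plate cells, had 3535 bp in replicate 1 and 4917 bp in replicate 2. Pax1 and Pax9, genes of the sclerotome beside the neural tube, had 1517 and 3805 bp in replicate 1 and 2811 and 5070 bp in replicate 2. The mesenchyme, cartilage and meninges list that holds both lay at percentile 83.6, with a median of 2 bp. In it 10 genes were wider in replicate 1 and 11 in replicate 2. Other single genes were wider in replicate 1, such as Hmx1 (5304 and 2960 bp) and Runx1 (7636 and 5454 bp).

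Posterior Hox genes differed most. In groups 10 to 13, 11 of 12 genes were wider in replicate 2, by a median of 1041.5 bp against -52 bp in matched lists, and Hoxc12, Hoxc13, Hoxd12 and Hoxd13 were the 4 genes with the largest gain of all. The size depended on the window, with a median of 2562.5 bp at 10 kb, and was 906.5 bp at the stricter threshold. The percentile of groups 10 to 13 was 100 among lists matched on covered length, so genes of like covered length did not shift alike. That cannot settle a difference in sensitivity between the lists, since the group was picked by this same comparison. Peak fold was not matched, depth is unknown, and neighbouring Hox genes share peaks, unlike genes drawn at random. The 123 genes of the other transcription factor lists had a median difference of 7 bp, so they did not widen by a like amount. Groups 10 to 13 lay at percentile 100 among lists drawn from these genes. That percentile cannot settle a general widening at developmental factors, since the group was picked by this comparison and covered length was not matched. Among lists matched on covered length, dorsal genes lay at percentile 99.4 and forebrain and midbrain factors at 99.9. Spinal factors lay at 32.3 and non-neural factors at 79.04. A smaller general widening stays open. More caudal tissue in the replicate 2 sample may account for the wider posterior Hox genes and stays open. Among the 27 Hox genes of groups 1 to 9 the difference did not follow paralog number (Spearman's rho -0.0816 and Pearson's r -0.01). However, 16 of these genes were at the full window in both replicates, so the measure was saturated. Over all 39 Hox genes rho was 0.50. That value includes the genes that showed the pattern and neighbours that share peaks, so it is no separate test of caudal tissue.

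Neural crest and peripheral neuron genes were wider in replicate 1 in 13 of 20 cases, by a median of -200.5 bp. An overall difference in sensitivity cannot be told apart here, since the percentile among matched lists was 2.14 and 9 of 24 lists lay in the outer 5% of theirs. With a 10 kb window the percentile was 0.15 and at the stricter threshold 0.65. A larger share of sensory ganglion cells in the replicate 1 sample is a candidate explanation that stays open. A separate list of 23 sensory ganglion genes lay at percentile 10.8, with 13 genes wider in replicate 1 and 4 in replicate 2, but the other 6 had 0 bp in both and could not show a difference. Without them the median of the 17 covered genes was -234 bp, at percentile 0.885. Its genes included Pirt (2952 and 1654 bp) and Tlx2 (5023 and 4040 bp). A list of Schwann and satellite glia genes lay at percentile 91.0, with 4 genes wider in replicate 1 and 5 in replicate 2. A list of sclerotome and paraxial mesoderm genes lay at 98.6, with 6 genes wider in replicate 1 and 8 in replicate 2.

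CTCF sites lay beside the summits of distal peaks, with 345 occurrences at 100 to 250 bp against 23 in the background and 15 against 17 within 100 bp. Base composition is argued against by other orders of the letters of the consensus, chosen so that like the consensus they cannot hold CG. Over 100 such orders the ratio of peak to background windows was 0.977 in total and 3.35 at most, against 10.1 for the consensus. A first test, with any order, met the bound set for base composition and was replaced after its result was seen, because the 14 of 100 orders that reached the ratio were all absent from the background. Repeats are argued against, since 329 of the 352 peak windows with the site kept it with masked occurrences left out (ratio 13.7). Marked nucleosomes on either side of a bound site may produce this, since occurrences per kb were 5.87 times as frequent at 100 to 250 bp as at 250 to 500 bp. Whether CTCF was bound in this tissue was not measured.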
